A study of Mus musculus with 9 samples.

How the data were processed

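RNA from 9 mouse liver samples was analysed in 4 groups named in the labels by treatment and vaccine (sham v-CTRL, n = 2; sham v-A12, n = 2; CCl4 v-CTRL, n = 2; CCl4 v-A12, n = 3), all at week 6. Per the labels' protocols, TRA and TRB transcripts were amplified by arm-PCR, a nested multiplex amplification, from 50 ng of total RNA and sequenced as paired-end reads of 250 nt. The aligner, the clonotype caller, its filters and the genome build are not given in the sources used here. Amplification of this kind multiplies each template many times, so that a read is not a molecule, a clone with a few templates can hold a large share of the reads, and copying errors appear as rare sequences close to common ones.

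For the sham livers the authors deposited counts: whole-number reads per CDR3 nucleotide sequence with its peptide and its V, D and J segments, not normalized. The lowest count in these tables was 2 reads. Rows whose sequence was out of frame name no peptide; they held 0.332% and 0.349% of TRB reads in sham v-CTRL replicates 1 and 2, 0.993% and 11.2% in sham v-A12 replicates 1 and 2, and 26.5% and 18.1% of TRA reads in sham v-CTRL and sham v-A12 replicate 1. They were not tested as clonotypes but were kept in the library size, which was fixed before the data were examined as all reads of a table, and in the V and J shares. Counts were summed over nucleotide sequences per peptide. Peptides were printed in the tables without the anchoring cysteine and phenylalanine.

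For the CCl4 livers the deposited tables list CDR3 peptides with a whole-number score or a blank per library. The lowest score stood for at least 2 reads wherever a total was determined, so a blank may mean fewer. It is called no reads or none below. No source states the scale. It was worked out from the values: the lower block of the v-A12 TRA table equalled the upper block divided by 100000 in all 20 rows of each library, which makes the upper block reads per 10000000, rounded down, if the lower block is a percent. For every library a total of reads between 20000 and 80000 was sought. At it, each score had to fall on a whole number of reads after rounding down. For each library 1 or 2 totals fitted, except for the TRB table of CCl4 v-A12 replicate 1, which has 1 score and no determined total. A total 2 times as large as one that fits also fits, so the scores set no upper bound. The smallest fitting total was taken, and the read counts and intervals of the CCl4 livers rest on that choice. All 38 and 42 TRA scores of CCl4 v-CTRL replicates 1 and 2 fell on whole reads, and the lowest stood for 2 reads. The rule by which the authors chose the listed peptides is not given in the sources used here.

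Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Clonotypes with at least 10 reads summed and seen in at least 2 libraries, and TRBJ and TRBV segments, were tested between sham v-A12 and sham v-CTRL on the counts with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Diversity was measured as Shannon entropy (natural log) after thinning each library to the peptide reads of the shallowest one (43483 for TRB, 35601 for TRA, 200 draws), with inverse Simpson index, clonality and richness beside it. Overlap was measured with the Morisita-Horn index. Differences between group means were tested with two-sided exact permutation tests, within vaccine for CCl4 against sham. Shares of single libraries carry exact Clopper-Pearson intervals. A peptide 1 residue away from a peptide at least 20 times commoner in the same library was called a near-neighbour and merged into it, and the peptides left are called founders. Founder nucleotide sequences were counted with the same ratio.

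On simulated TRBJ counts of 11 segments with 10-fold changes, edgeR's test called 0.6% of the changed segments at the dispersion estimated from the livers (3.10) and 100% at a dispersion of 0.05; for 18 TRBV segments it called 0% at the estimated dispersion of 8.53. At the spread seen between these livers, most simulated changes of 10-fold were therefore missed. The simulated library size was held fixed, so a 10-fold rise of a common segment could exceed all reads of its library. Shares cannot do so, and the simulation does not measure power for common segments. The labels speak of mice but do not tie each library to a separate animal in so many words, so p-values measure the spread between these samples.

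Peptides were named by a rule fixed before the data were examined: the 3 commonest in each library of over 30 rows and the 5 commonest in smaller ones; those past the threshold, or of smallest p where none passed; up to 5 read in every library of 1 group and none of the compared group; up to 5 read in every library of a chain; and the members of lists of TRBJ endings, TRBV starts, iNKT-like TRA and MAIT-like TRA junctions. The sham tables name the segments, so the TRBJ and TRBV lists were matched to those names; of 98 segment names 91 were found in the gene table of assembly GRCm38.p6, which was used for names only. No coordinates are given, since no build is named. Alternatives tried were other scaling, filters, DESeq2, founders or distinct peptides in place of reads, other diversity and overlap measures, each replicate left out, and the replicate number as a block. Tests of TRBV usage, of founder peptides, of in-frame reads only and of other denominators for the invariant chain were added after the data were seen.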

Results

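T cell receptor alpha (TRA) and beta (TRB) transcripts were sequenced in 9 liver samples of wild-type mice at week 6. The mice had been vaccinated with an ADAM12 vaccine (v-A12) or a control vaccine (v-CTRL) and were then given carbon tetrachloride (CCl4), a hepatotoxin used to produce liver fibrosis, or olive oil alone (sham); both were dosed 3 times per week over 6 weeks. ADAM12 is a transmembrane metalloprotease expressed by activated mesenchymal cells. The groups held 2 sham v-CTRL, 2 sham v-A12, 2 CCl4 v-CTRL and 3 CCl4 v-A12 livers, and the design asks how vaccination and liver injury relate to the T cell repertoire of the tissue. The measured unit was the CDR3, a part of each receptor chain that contacts the antigen. It is built at the junction of the V and J segments, with a D segment between them in TRB only.

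The sham TRB tables held 49048 and 46665 reads for v-CTRL replicates 1 and 2 and 43919 and 50535 reads for v-A12 replicates 1 and 2. The sham TRA tables, analysed for replicate 1 of each vaccine, held 48440 reads for v-CTRL and 47881 reads for v-A12. TRA tables of sham replicate 2 were not analysed here. The CCl4 tables were short lists of peptides scaled to 10000000 reads. The smallest library totals that fit the spacing of their values were 41916 and 30350 TRA reads for v-CTRL replicates 1 and 2. For v-A12 replicates 1 to 3 they were 39519, 32545 and 31672. The reads carried no molecular identifiers, so the 95% Clopper-Pearson intervals given with single shares cover counting error only.

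The TRB reads of both sham v-A12 livers fell on fewer peptides than those of either sham v-CTRL liver. The v-CTRL livers held 295 and 230 distinct TRB CDR3 peptides and the v-A12 livers 98 and 131, which gave means of 262.5 ± 46.0 and 114.5 ± 23.3 (SD, n = 2 each), a ratio of 2.29. The 10 commonest peptides took 32.96% and 38.9% of the reads in the v-CTRL livers and 93.8% and 74.3% in the v-A12 livers. The commonest peptide alone took 4.93% and 5.11% of the v-CTRL reads, against 19.6% and 10.3% of the v-A12 reads. Most distinct peptides differed by 1 residue from a peptide at least 20 times commoner in the same library. After these were merged into the commoner peptide, 74 and 47 founder peptides were left in the v-CTRL livers and 16 and 20 in the v-A12 livers, a 3.36-fold ratio of means (60.5 ± 19.1 against 18 ± 2.83, SD, n = 2).

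**Figure D1:**
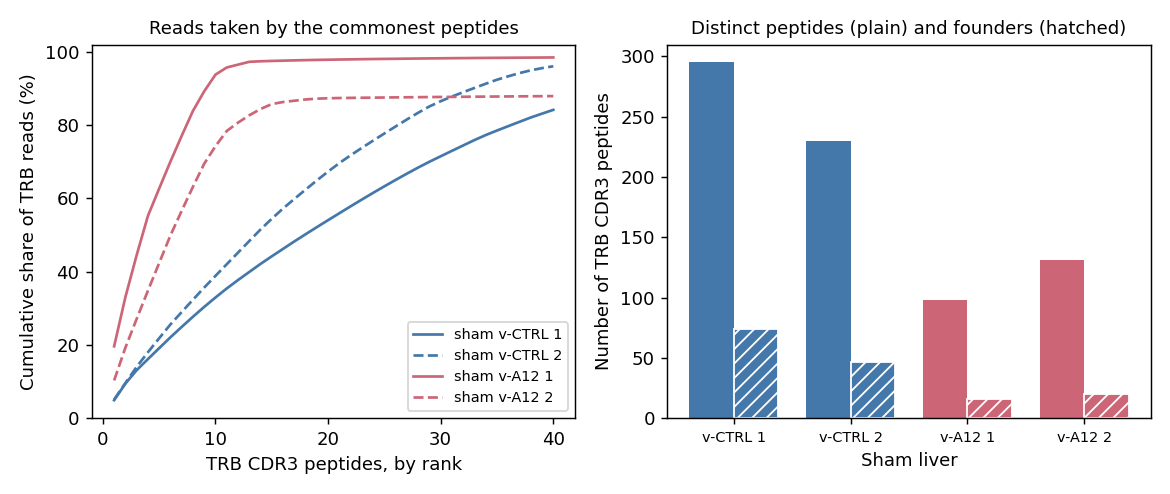
Left, cumulative share of TRB reads (%) against the rank of the CDR3 peptide for each sham liver; right, number of distinct TRB CDR3 peptides (plain bars) and of founder peptides (hatched bars) per liver. The 10 commonest peptides reached 93.8% and 74.3% of reads in the v-A12 livers and 32.96% and 38.9% in the v-CTRL livers. Shares are of all TRB reads, out-of-frame reads included. These held 11.2% in v-A12 replicate 2, whose curve therefore stood at 87.9% at rank 40, and under 1% in the other livers.

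Shannon entropy of the TRB peptides, thinned to 43483 reads per library, was 4.07 and 3.74 in the v-CTRL livers and 2.43 and 2.76 in the v-A12 livers. The group means of 3.91 ± 0.229 and 2.60 ± 0.234 (SD, n = 2) differed by -1.31, a distance larger than either spread (two-sided exact permutation p = 0.333). With 2 livers per group 0.333 was the smallest p the exact test allowed, so no difference in diversity could pass the 0.05 threshold. Inverse Simpson diversity was 40.5 ± 7.90 in v-CTRL and 11.1 ± 2.78 in v-A12 livers, and clonality was 0.298 ± 0.0191 and 0.451 ± 0.0256 (SD, n = 2).

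Each of the dominant TRB clonotypes was read in 1 liver only. In v-A12 replicate 1 they were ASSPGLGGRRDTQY (TRBV14, TRBJ2-5; 19.6% of reads), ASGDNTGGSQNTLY (TRBV13-2, TRBJ2-4; 13.4%) and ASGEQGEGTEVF (TRBV13-2, TRBJ1-1; 11.5%). In v-A12 replicate 2 they were ASKSGSSAETLY (TRBV13-1, TRBJ2-3; 10.3%), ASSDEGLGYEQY (TRBV13-1, TRBJ2-7; 8.95%) and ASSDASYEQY (TRBV13-3, TRBJ2-7; 7.84%). In v-CTRL replicate 1 they were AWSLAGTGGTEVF (TRBV31, TRBJ1-1; 4.93%), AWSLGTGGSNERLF (TRBV31, TRBJ1-4; 4.53%) and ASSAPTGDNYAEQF (TRBV13-1, TRBJ2-1; 3.67%). In v-CTRL replicate 2 they were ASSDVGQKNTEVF (TRBV13-1, TRBJ1-1; 5.11%), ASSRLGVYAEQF (TRBV12-1, TRBJ2-1; 4.49%) and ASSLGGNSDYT (TRBV12-1, TRBJ1-2; 4.43%).

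Of 753 TRB peptides in the 4 sham livers, 752 were read in 1 liver and 1 in 2 livers. The libraries yielded between 16 and 74 TRB founder peptides each, so a peptide not read in a liver is not shown to be absent from it. The shared peptide was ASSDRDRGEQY (TRBV13-1, TRBJ2-7), with 3 reads (0.00612%) in v-CTRL replicate 1 and 804 reads (1.72%) in v-CTRL replicate 2, from 1 identical nucleotide sequence. The 3 reads lay near the lowest count of 2, and whether they came from that liver was not tested. Overlap between the v-CTRL livers was accordingly near 0 (Morisita-Horn index 4.22e-05), the v-A12 livers shared 0 peptides, and each of the 4 pairs of livers with different vaccines shared 0. The index within vaccine groups exceeded that between them by 2.11e-05 (one-sided exact permutation p = 0.333 over 3 splits, the smallest possible). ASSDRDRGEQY was also the 1 peptide with at least 10 reads summed and reads in at least 2 libraries. Its log2 fold change of v-A12 over v-CTRL was -11.68, which depends on the prior count. It did not pass edgeR's quasi-likelihood test (edgeR Benjamini-Hochberg adjusted p = 0.317). Thus 0 clonotypes passed, with 0 at an unadjusted p under 0.05, whereas DESeq2 called this peptide lower in v-A12 (adjusted p = 0.0144).

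TRBV13-2 (V beta 8.2) and TRBV13-1 (V beta 8.3), of the V beta 8 family, were the leading V segments of the sham livers. TRBV13-2 took 33.4% and 31.8% of TRB reads in the v-CTRL livers and 58.5% and 19.4% in the v-A12 livers, and TRBV13-1 took 28.3% and 29.1% against 0 reads and 38.5%; in the last of these livers, in-frame TRBV13-1 reads were 27.4% of all TRB reads. V beta 8.2 is the commonest beta segment of mouse invariant natural killer T (iNKT) cells, lymphocytes that recognise lipids and are abundant in mouse liver. Among J segments, TRBJ2-5 took 4.18% and 1.17% of reads in v-CTRL and 20.2% and 15.1% in v-A12 livers (means 2.67 ± 2.13% and 17.6 ± 3.61%, SD, n = 2), while TRBJ1-1 took 22.7% and 22.4% against 11.6% and 1.39%. TRBJ2-5 had 3 and 1 founder peptides in the v-CTRL livers and 1 and 4 in the v-A12 livers. TRBJ1-1 had 15 and 10 against 1 and 1. The TRBJ2-5 shares of all livers and the TRBJ1-1 shares of the v-A12 livers thus rested on few chains. TRBJ2-7 took 23.9%, 26.2% and 24.9% of reads in both v-CTRL livers and v-A12 replicate 2. It had no row in v-A12 replicate 1, whose reads came from 16 founder peptides.

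No segment passed edgeR's test, although the TRBJ2-5 and TRBJ1-1 means lay further apart than the SD of either group. The same held for TRBJ1-2, TRBJ1-3, TRBJ1-5 and TRBV12-1. Of the 12 TRBJ segments listed beforehand 11 were seen; the v-A12 mean was above the v-CTRL mean for 6 and below it for 5, and 0 passed edgeR's quasi-likelihood test, either over all 11 or adjusted over the list alone (smallest adjusted p = 0.853, 0 at an unadjusted p under 0.05). For TRBJ2-5 the log2 fold change was 2.72 (edgeR adjusted p = 0.853) and for TRBJ1-1 it was -1.80 (edgeR adjusted p = 0.897). Of the 7 TRBV segments listed beforehand 5 were seen (TRBV13-2, TRBV1, TRBV31, TRBV19 and TRBV17; 3 higher and 2 lower in the v-A12 mean), TRBV20, TRBV30 and TRBJ2-2 had no row, and 0 passed edgeR's test adjusted over the list alone; over all 18 TRBV segments, a test added after the data were seen, 0 passed (edgeR, smallest adjusted p = 0.597, 0 at an unadjusted p under 0.05). DESeq2 called 1 TRBJ segment, TRBJ1-6, and 4 TRBV segments, TRBV12-2, TRBV16, TRBV17 and TRBV4, each with reads in 1 liver. Leaving out v-A12 replicate 1 gave 3 edgeR calls (TRBJ1-1 and TRBJ2-4 lower, TRBJ1-4 higher in v-A12), and leaving out v-A12 replicate 2 also gave 3 (TRBJ1-4, TRBJ2-1 and TRBJ2-7, all lower). The TRBJ1-4 call in replicate 2 (17.6% of reads, against a v-CTRL mean of 6.26%) rested on 1 out-of-frame TRBV13-1 and TRBJ1-4 sequence of 5428 reads; counting in-frame reads only, an alternative added after the data were seen, TRBJ1-4 took 6.52% of all reads there and 2 calls were left (TRBJ1-1 and TRBJ2-4). In these fits the lone v-A12 liver was assumed to vary like the v-CTRL livers.

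**Figure D2:**
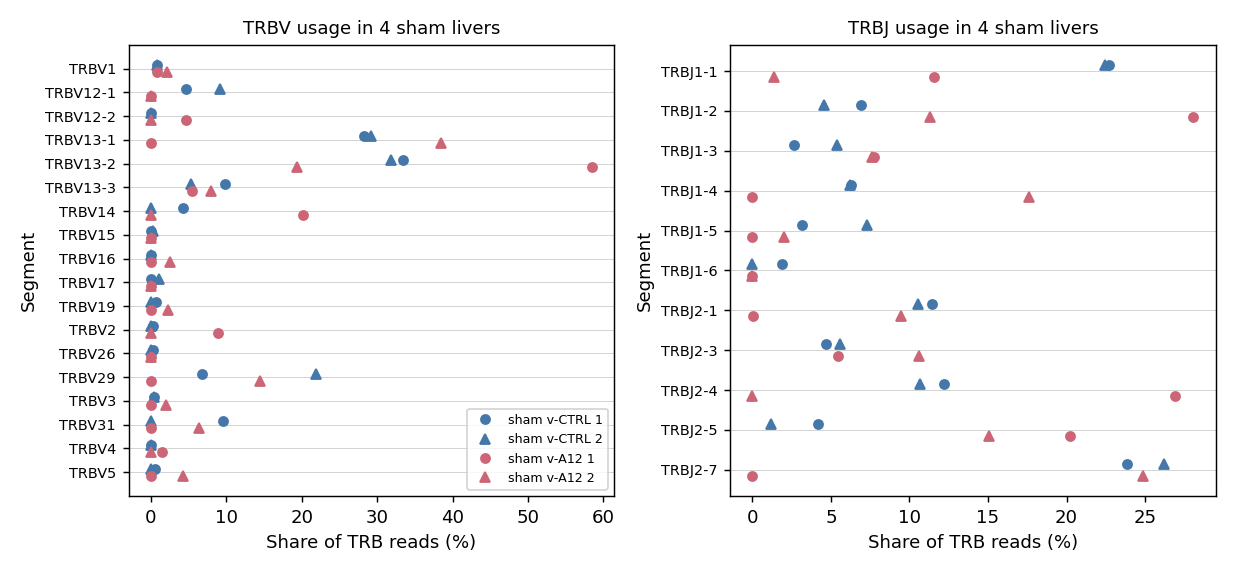
Share of TRB reads (%) of each TRBV segment (left) and TRBJ segment (right) in the 4 sham livers; circles are replicate 1, triangles replicate 2, blue v-CTRL and red v-A12. The v-CTRL livers lay close together for TRBV13-1 (28.3% and 29.1%) and TRBJ1-1 (22.7% and 22.4%), and the v-A12 livers lay apart (0 and 38.5%, and 11.6% and 1.39%).

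The alpha chain of iNKT cells led both sham TRA repertoires. VVGDRGSALGRLH, the invariant junction of TRAV11 with TRAJ18, took 17.9% of TRA reads in sham v-CTRL (8652 reads, interval 17.5 to 18.2%) and 24.8% in sham v-A12 (11859 reads, interval 24.4 to 25.2%), a difference of 6.91 percentage points. It was encoded by 4 founder nucleotide sequences in each liver, of 44 in v-CTRL and 21 in v-A12, which ranged from 1773 to 3110 reads and from 887 to 4778 reads. All peptides with that junction summed to 18.1% of reads in v-CTRL (4 peptides) and 24.8% in v-A12 (5 peptides), and those with the untrimmed TRAJ18 ending after any V segment to 18.8% and 24.8% (7 peptides in each). By the tables' own segment names, which include trimmed endings, TRAJ18 held 9193 and 13134 in-frame reads. The alpha chain of mucosal-associated invariant T (MAIT) cells, built from TRAJ33, had no row in either table. The next commonest peptides were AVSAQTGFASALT (TRAV9D-4, TRAJ35; 8.68%) and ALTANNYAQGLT (TRAV12D-1, TRAJ26; 6.36%) in v-CTRL, and AMRGTASLGKLQ (TRAV13D-4, TRAJ24; 14.7%) and VLGDVGYKLT (TRAV6-1, TRAJ9; 9.02%) in v-A12.

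The v-CTRL liver held 120 distinct TRA peptides and 38 founders, and the v-A12 liver 83 and 18; Shannon entropy was 2.80 and 2.28. Few TRA peptides were read in both livers. With 38 and 18 founders, a peptide not read in a liver is not shown to be absent from it. The livers shared 8 peptides, which were VVGDRGSALGRLH and 7 peptides 1 residue away from it, and after merging they shared 1 founder. With 1 liver per vaccine these TRA differences compare the livers and not the vaccines, and no test was made.

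In the CCl4 livers the TRA lists of the vaccine groups had few peptides in common. AINSAGNKLT led the listed peptides in both v-CTRL livers, with 3.89% and 7.53% of TRA reads (mean 5.71 ± 2.57%, SD, n = 2). In the v-A12 livers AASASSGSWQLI took 1.85% and 15.2% of reads in replicates 1 and 2 and none in replicate 3. There ALSDRTNAYKVI led the listed peptides with 1.04% (interval 0.927 to 1.15%). The listed peptides together held 9.33% and 17.0% of TRA reads in v-CTRL replicates 1 and 2. In v-A12 replicates 1 to 3 they held 5.95%, 17.7% and 2.97%. An unlisted peptide may therefore have been commoner in any of these livers. Of 87 TRA peptides on either list, 2 were on both, VVGDRGSALGRLH and the peptide VVVDRGSALGRLH, which also has the invariant TRAJ18 junction. The deposited lists carry no rule by which peptides were chosen, so a peptide missing from a list is not shown to be missing from the liver. The v-CTRL livers also shared only 11 of their 69 listed peptides, while each of the 20 v-A12 peptides had reads in at least 2 livers. The difference between the lists is therefore not shown to follow the vaccine.

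The v-CTRL list named 69 TRA peptides, of which 11 had reads in both livers and 58 in 1 liver. The v-A12 list named 20, each with reads in at least 2 of the 3 livers. Peptides with reads numbered 38 and 42 per v-CTRL liver and 17, 14 and 12 per v-A12 liver, a difference of means of -25.7 (40 ± 2.83, n = 2, against 14.3 ± 2.52, n = 3, SD; two-sided exact permutation p = 0.1, the smallest possible). The direction of this difference was fixed by the lists, since a v-A12 liver could hold at most the 20 listed peptides, so it does not compare the livers. The share of TRA reads that the lists covered was 13.2 ± 5.41% in v-CTRL (n = 2) and 8.87 ± 7.78% in v-A12 livers (n = 3), less apart than the spread (exact permutation p = 0.6). This share too depends on the lists of 69 and 20 peptides, whose rule of choice is not known, so it does not compare the livers.

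Among peptides read in both v-CTRL livers and in none of the v-A12 tables, ALSSNTNKVV followed AINSAGNKLT with a mean of 0.590 ± 0.507% and ALRQQGTGSKLS had 0.331 ± 0.408% (SD, n = 2), with AASNNNNAPR at 0.0543% and ATNSAGNKLT at 0.0223%. ATNSAGNKLT is 1 residue from AINSAGNKLT and had 0.552% and 0.306% of its reads in replicates 1 and 2. Other leading listed peptides of these livers were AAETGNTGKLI at 0.491% in replicate 1 and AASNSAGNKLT at 1.08% in replicate 2. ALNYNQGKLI was the 1 peptide read in all 3 v-A12 livers and in neither v-CTRL table, with 0.129%, 0.332% and 0.619% of reads (mean 0.360 ± 0.246%, SD, n = 3). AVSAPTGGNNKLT had 0.354% and 0.366% in v-A12 replicates 1 and 2, AASGDTNAYKVI 0.602% in replicate 1, ALSDRTNAYKVI 0.390% in replicate 2, and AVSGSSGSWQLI 0.142% in replicate 3. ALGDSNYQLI, which carries the TRAJ33 ending, had 0.321% and 0.123% in replicates 1 and 3. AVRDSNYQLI, with the MAIT junction, had 0.0557% of TRA reads in v-A12 replicate 1, 0.138% in replicate 2 and none in replicate 3, and was not on the v-CTRL list.

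The invariant iNKT chain was read in all 5 CCl4 livers, and its share differed between the vaccines by less than the spread between livers. VVGDRGSALGRLH took 1.25% and 0.975% of TRA reads in the v-CTRL livers and 2.16%, 1.08% and 0.710% in the v-A12 livers (1.11 ± 0.193%, n = 2, against 1.32 ± 0.755%, n = 3; two-sided exact permutation p = 0.9). VVVDRGSALGRLH took 0.165 ± 0.0041% in v-CTRL and 0.0411 ± 0.0233% in v-A12 livers (exact permutation p = 0.1, the smallest possible).

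The CCl4 TRB lists were shorter. The v-CTRL list named 3 peptides, all read in both livers and led by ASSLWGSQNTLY with 0.601% and 0.778% of TRB reads; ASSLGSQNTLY averaged 0.0676% and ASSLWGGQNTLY 0.0140%. The v-A12 list named 5. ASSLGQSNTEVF had 0.743% and 2.17% in replicates 2 and 3 and none in replicate 1, and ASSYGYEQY had 0.0305% and 0.475% in replicates 1 and 3. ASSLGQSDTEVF, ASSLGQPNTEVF and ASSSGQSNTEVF, each 1 residue from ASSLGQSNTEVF, had between 2 and 4 reads in the livers where they were found. The number of TRB peptides with reads was 3.00 in each v-CTRL liver and averaged 3.33 ± 2.08 in v-A12 livers (n = 3, exact permutation p = 1). The lists of 3 and 5 peptides capped these counts, so they do not compare the livers.

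Between treatments, the invariant iNKT alpha chain took a far smaller share of TRA reads in the CCl4 tables than in the sham tables. The 5 CCl4 livers lay between 0.710% and 2.16% (1.24 ± 0.554%, SD, n = 5) and the 2 sham livers at 17.9% and 24.8% (21.3 ± 4.88%, SD, n = 2), a 17.2-fold ratio. Within vaccines the ratio of sham to CCl4 was 16.1 for v-CTRL and 18.8 for v-A12. The mean of the within-vaccine differences was -20.1 percentage points (two-sided exact permutation within vaccine, p = 0.0833, the smallest that 12 arrangements allow). As shares of only the listed or equally many top peptides the difference was -11.6 points (exact permutation p = 0.333), and the livers overlapped: the sham livers stood at 24.4% and 30.5%, the CCl4 v-CTRL livers at 13.4% and 5.74%, and the CCl4 v-A12 livers at 36.4%, 6.11% and 23.9%. All sham values came from full tables of counts and all CCl4 values from selected lists, so kind of table and treatment cannot be told apart.

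**Figure D3:**
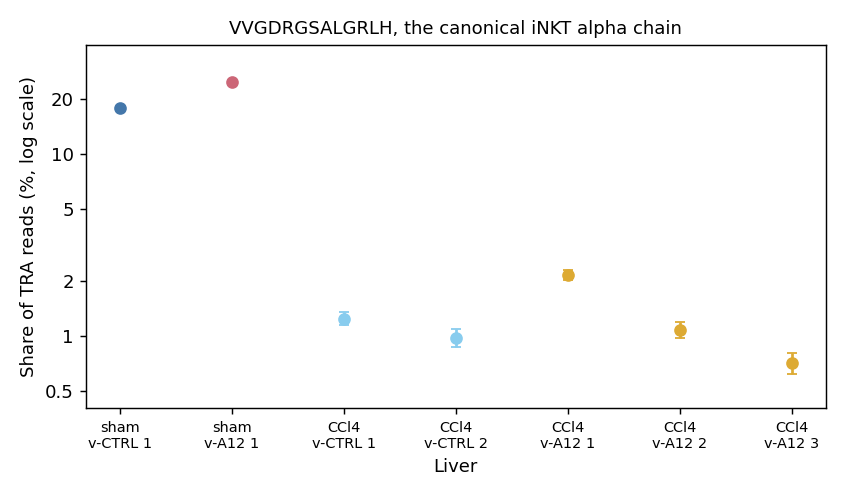
Share of TRA reads (%, logarithmic axis) of the peptide VVGDRGSALGRLH in each liver whose TRA table was analysed; bars are 95% Clopper-Pearson intervals, which are smaller than the points for the sham livers. The sham livers stood at 17.9% and 24.8% and the CCl4 livers between 0.710% and 2.16%.

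Beyond this chain the listed CCl4 peptides were not found in the sham tables. Of the 87 listed CCl4 TRA peptides 1, VVGDRGSALGRLH, was in a sham TRA table, and of the 8 listed CCl4 TRB peptides 0 were in a sham TRB table. VVGDRGSALGRLH was also the 1 TRA peptide read in all 7 livers whose TRA table was analysed.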

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

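TRB reads without an in-frame CDR3 peptide, which were not tested as clonotypes, took 0.993% of reads in sham v-A12 replicate 1 and 11.2% in sham v-A12 replicate 2, above the 0.332% and 0.349% in the sham v-CTRL livers. In replicate 2 of sham v-A12, 1 out-of-frame TRBV13-1 and TRBJ1-4 sequence held 5428 reads (10.7%), and in replicate 1 a TRBV4 and TRBJ2-4 sequence held 280 reads (0.638%). TRBJ1-4 held 17.6% of all reads in replicate 2, and 6.52% when only its in-frame reads were counted.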

How the results depend on the processing

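With 1 to 3 livers per group no exact test could pass 0.05, so the alternatives show direction and size only. The lower TRB diversity of sham v-A12 had the same direction under all 11 alternatives, with Shannon differences of -1.47 to -1.14 when 1 liver was left out. Some of these could not differ in direction. The replicate block equals the difference of means by construction, and leaving out 1 liver cannot reverse groups that do not overlap. The excess overlap within groups rests on 1 peptide. With 0 peptides shared between groups, none of its 3 alternatives could make it negative, so they show nothing about stability. The count of TRA peptides with reads in CCl4 v-A12 minus v-CTRL (-27.7 to -23.7 with 1 liver left out) has a direction fixed by the lengths of the lists, so its alternatives show nothing about stability. The mean share of the invariant chain was lower in CCl4 than sham under all 9 alternatives, of which matching with anchor residues left the -20.1 points unchanged. Leaving out a CCl4 liver gave -20.3 to -19.9 points. With 1 sham liver per vaccine, leaving out a sham liver removed its whole vaccine. This gave -23.4 points for v-A12 alone and -16.7 for v-CTRL alone. As a share of listed peptides (-11.6 points) CCl4 v-A12 replicate 1 lay above both sham livers.

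The 0 calls of edgeR became 1 for TRBJ, 4 for TRBV and 1 for clonotypes with DESeq2, and between 0 and 3 for TRBJ with 1 liver left out; leaving out a liver kept TRBV and clonotypes at 0. With in-frame reads only, added after the data were seen, TRBJ and TRBV stayed at 0 calls, and TRBJ had 2 without v-A12 replicate 1 and 3 without v-A12 replicate 2. These calls rest on segments or peptides read in 1 or 2 livers or on a lone liver's spread taken from the other group. The invariant chain's sham difference of 6.91 points was 5.90 as a share of productive reads, added after the data were seen, by the change of denominator. Its values of 0.371 as a share of distinct peptides and, also added, 9.96 as a share of founder nucleotide sequences show nothing about its abundance, since it is 1 peptide with 4 founders in both livers and only the totals differ. For the same reason the 2.69 for all peptides with the junction as a share of distinct peptides (6.75 of reads) reflects mainly the totals.

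The replicate block left TRBJ calls at 0 (edgeR, smallest adjusted p = 0.774). Shannon entropy differed by -1.31 within replicate numbers, which equals the difference of group means by construction. Deviations of same-numbered livers correlated at 0.152 over TRBJ and -0.0174 over TRBV segments, so the numbers are not shown to pair livers. The block gave no value for the 1 tested clonotype, leaving out either v-CTRL liver left no clonotype to test, and alternatives that drop peptides of 1 read were not run because the lowest count is 2. Thinning removed few reads and left the Shannon difference at -1.31, so it tests little.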

Other observations

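Segment use beyond the tested TRB lists also differed between single livers. The sham v-CTRL liver had reads of 33 TRAV and 27 TRAJ segments, in or out of frame, and the sham v-A12 liver of 22 and 17. Counting in-frame reads as a share of all TRA reads, TRAV9D-4 and TRAV9D-3 held 14.5% and 9.72% in v-CTRL and had no row in v-A12, while TRAV13D-4 held 2 reads in v-CTRL and 15.1% in v-A12. Out-of-frame sequences held 3347 of the 3349 TRAV13D-4 reads of v-CTRL and 4817 of the 4819 TRAV6D-5 reads of v-A12. TRAJ18, the J segment of the invariant chain, held 9205 of 48440 TRA reads in v-CTRL and 13140 of 47881 in v-A12. Mean CDR3 length differed by less than the spread between livers: distinct TRB peptides averaged 12.3 ± 0.316 residues in sham v-CTRL and 12.3 ± 0.348 in sham v-A12 livers (SD, n = 2; exact permutation p = 0.667).

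The tests of the first pair of patterns that follow were chosen after the results were seen; the test of the last was written before its ratios were computed. The sham v-A12 livers held fewer TRB clonotypes. A difference in read depth is argued against, since mean TRB reads had a v-CTRL to v-A12 ratio of 1.01 and distinct peptides one of 2.29, and so are copying errors of common chains, since the ratio of founders was 3.36. Fewer T cell templates in the input RNA stay open: TRA founders of replicate 1 also had a ratio of 2.11, which a narrower repertoire would give as well, and without molecular identifiers these cannot be told apart. A vaccine effect on the resident T cells is a hypothesis that 2 livers per group could not test.

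The share of all TRA reads taken by the invariant iNKT chain was lower in the CCl4 tables. A 10-fold smaller scale is argued against, because on it the largest list would sum to 176.9% of its library. Other scales were not tested. Whether the totals behind the scores include out-of-frame reads, as the sham totals do, is not known. Few sequenced templates behind the shares could move them and stay open: 4 founder nucleotide sequences carried the chain in each sham liver, and neither kind of table counts templates. A difference in how the tables were made also stays open, since the number of treatments that have both kinds of table is 0. An effect of CCl4 on iNKT cells therefore remains untested.

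The CCl4 lists hold peptides 1 residue from a commoner peptide of the same library, 36 such pairs over 21 of the 97 listed entries (1 tied pair was left out after its ratio was seen). In the sham tables, 737 such pairs had a median ratio to the commoner peptide of 0.294% and a 95th percentile of 1.10%. Of the CCl4 pairs 21, or 58.3%, covering 12 listed entries, lay at or below that percentile, so copying errors may account for these. Among them were the 3 neighbours of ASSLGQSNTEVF, those of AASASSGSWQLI, and ATNSAGNKLT beside AINSAGNKLT. Since the lowest score stood for at least 2 reads, a pair with a scarce commoner peptide could only lie above the percentile. ALSGRTNAYKVI in v-A12 replicate 2, with 2 reads beside 127 (1.57%), was such a pair. For such pairs the percentile decides nothing. The pairs above the percentile include VVVDRGSALGRLH in 4 of 5 livers, up to 17.2% of the invariant chain, which copying at the sham rate would not give. No biological explanation was tested.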
